A study of Mus musculus with 6 samples.

How the data were processed

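Bulk RNA-seq of 6 mouse cell samples was used: 3 carrying the T44 guide against Clec12a and 3 carrying the lacZ guide. Per the labels' protocols, cells were stimulated for 48 hours in medium with 15% serum, human interleukin-6 at 10 ng/mL, mouse interleukin-3 at 6 ng/mL and mouse stem cell factor at 20 ng/mL, and total RNA was extracted with a column kit for Illumina sequencing. Groups came from the sample labels, and column names matched the sample titles.

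The authors deposited 1 table of FPKM (fragments per kilobase of transcript scaled to the mapped fragments of the library) by gene symbol. Per the submitters' processing notes, FastQC, STAR 2.5.2b and the mm10 genome were used. The counting tool, the gene annotation, strand use and any filter are not given in the sources used here. FPKM corrects for gene length and total reads only, so a change in a few abundant genes, in fragment lengths or in RNA integrity moves many values at once.

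FPKM is no count, so no count test was run. The depth behind each value was estimated from genes with 1 annotated transcript (4153 genes), where FPKM times length should be a whole multiple of what 1 fragment is worth. The best-fitting depths were 50200000, 50900000 and 33600000 fragments for knockout replicates 1, 4 and 5 and 61000000, 47900000 and 45500000 for control replicates 6, 8 and 9. Between 62.6% and 69.6% of low values lay within 0.1 of a whole number up to 5, against 20.0% by chance, so whole reads were not recovered for nearly all genes and the depths are estimates. From 3489 to 6834 genes per library were listed at 0 and from 9561 to 9823 were at 1 FPKM or more.

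Symbols were matched to GENCODE M21 (GRCm38) for coordinates, transcript length and GC content: 21414 by symbol, 75 by synonym, and 26 not at all. Snhg4 was among those with no match, so no coordinates are given for it. Overlap of exons between genes was computed for Clec12a and the genes with the largest changes.

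Genes with FPKM of at least 1 in at least 3 libraries were kept (9830), and log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A gene is said to have risen, fallen or changed only past that threshold. Clec12a was also compared by an exact permutation test. Fixed gene lists (35, of which 33 had a tested member) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With the preset correlation 14 lists passed; with an estimated correlation none did (1 at an unadjusted p under 0.05, and adjusted p from 0.516 upward); with fry 2 passed in one direction and 20 in either direction. Members of each list were counted as adjusted over all genes and adjusted over the list alone.

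The groups, the main test, the filter, the pseudocount, the 35 lists, the rule for named genes and the other settings were fixed before the data were examined. The rule named Clec12a; the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, leaving out unnamed gene models; up to 4 members past the threshold per list, by lowest p, or the 2 with the highest mean where none passed; and it allowed any tested C-type lectin gene. Giving only those C-type lectin genes that passed when adjusted over the list alone was decided after the data were seen. A gene chosen after its values were seen is said to be so.

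The test was run on simulated data: 200 of 9830 genes were changed by known folds, with spreads taken from these libraries. It recovered 3% of 67 genes changed by 1.5-fold, 26.9% of 67 changed by 2-fold and 97% of 66 changed by 4-fold, with 5 false among 89 calls. Within that simulation, most changes under 2-fold were below what 3 against 3 libraries can show. Its noise was independent between genes, whereas these libraries share trends across genes. The recovery and the share of false calls therefore need not carry over to the real values.

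The settings planned in this way were pseudocounts of 0.1 and 0.01, no filter, a mean FPKM of at least 5, scaling by median ratios, by quantiles or to equal totals, limma without the trend, with a robust prior or with array weights, an adjusted p under 0.1, a 2-fold limit, and leaving out each library in turn. Added after seeing the data were a correction of each library for transcript length and GC content (splines with 4 degrees of freedom; 9820 genes had both values) and leaving out the genes of distal chromosome 15. Windows of 60 neighbouring genes along each chromosome, 10000 shuffles of gene order and 10000 bootstraps over genes were also added after seeing the data. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.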

Results

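RNA was measured in mouse bone marrow cells that had been immortalised with the leukaemia fusion NUP98-NSD1 and the activated RAS protein NRASG12D. Cas9 was delivered by lentivirus together with a guide RNA against Clec12a, an inhibitory C-type lectin receptor of myeloid cells, or a guide against the bacterial gene lacZ, which has no target in the mouse genome. Cells were sorted singly and expanded before RNA was isolated. There were 3 libraries from Clec12a knockout cells (replicates 1, 4 and 5) and 3 from lacZ control cells (replicates 6, 8 and 9), and the question was how losing Clec12a alters expression in these cells. The deposited FPKM covered 21515 genes, of which 1422 were at 0 in all 6 libraries. FPKM totals ran from 590211 to 699113 in knockout libraries and from 534440 to 554534 in controls, so the total went with the guide. Estimated depth ran from 33600000 to 61000000 fragments. The p-values measure the spread between these libraries, since how far the sorted cells within a group are independent is not given in the sources used here.

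Clec12a itself (chromosome 6, 129342691 to 129365303, GRCm38) was measured at 170, 129 and 94.5 FPKM in the knockout libraries and at 157, 246 and 280 FPKM in the controls. The knockout mean was 57.5% of the control mean (131 ± 37.6 against 228 ± 63.7 FPKM, SD, n = 3 each), but the groups overlapped. The log2 fold change was -0.79 (SE 0.29, 95% interval -1.45 to -0.13) with an adjusted p of 0.130, which did not pass the threshold. An exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest that 3 against 3 libraries allow. FPKM is summed over the whole gene, so a small edit in an exon need not lower it, and the level neither checks nor contradicts the labels.

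In knockout cells, some late neutrophil, chemokine, stress-response and adhesion genes rose, while the transcription factor gene Meis1 and 3 cell cycle genes (Ccne2, Kif20a and Kif23) fell. Ly6g, a surface marker of mature neutrophils, rose from 5.49 ± 3.18 to 74.9 ± 42.1 FPKM (log2 fold change 3.53, SE 0.52, adjusted p = 0.0215). Gdf15, a stress-induced secreted factor, rose from 0.297 ± 0.181 to 18.2 ± 4.86 FPKM (log2 fold change 3.86, SE 0.25, adjusted p = 7.01e-04). Ccl3, a chemokine that attracts monocytes, rose from 113 ± 17.0 to 531 ± 122 FPKM (log2 fold change 2.20, SE 0.24, adjusted p = 0.00687). Meis1, a cofactor of HOX proteins, fell from 26.8 ± 8.14 to 8.91 ± 1.68 FPKM (log2 fold change -1.46, SE 0.26, adjusted p = 0.0367). After a correction of each library for transcript length and GC content, Kif20a still passed (adjusted p = 0.0392), while Meis1 (adjusted p = 0.0565), Ccne2 (0.0522) and Kif23 (0.0529) did not, with lower values kept (log2 fold change -1.11, -1.12 and -0.90). Without knockout replicate 4, and so with fewer samples, neither Meis1 nor any of the 3 cell cycle genes passed. Values here and below are mean ± SD of 3 libraries, and fold changes are on the log2(FPKM + 1) scale, which understates those of low genes.

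**Figure D1:**
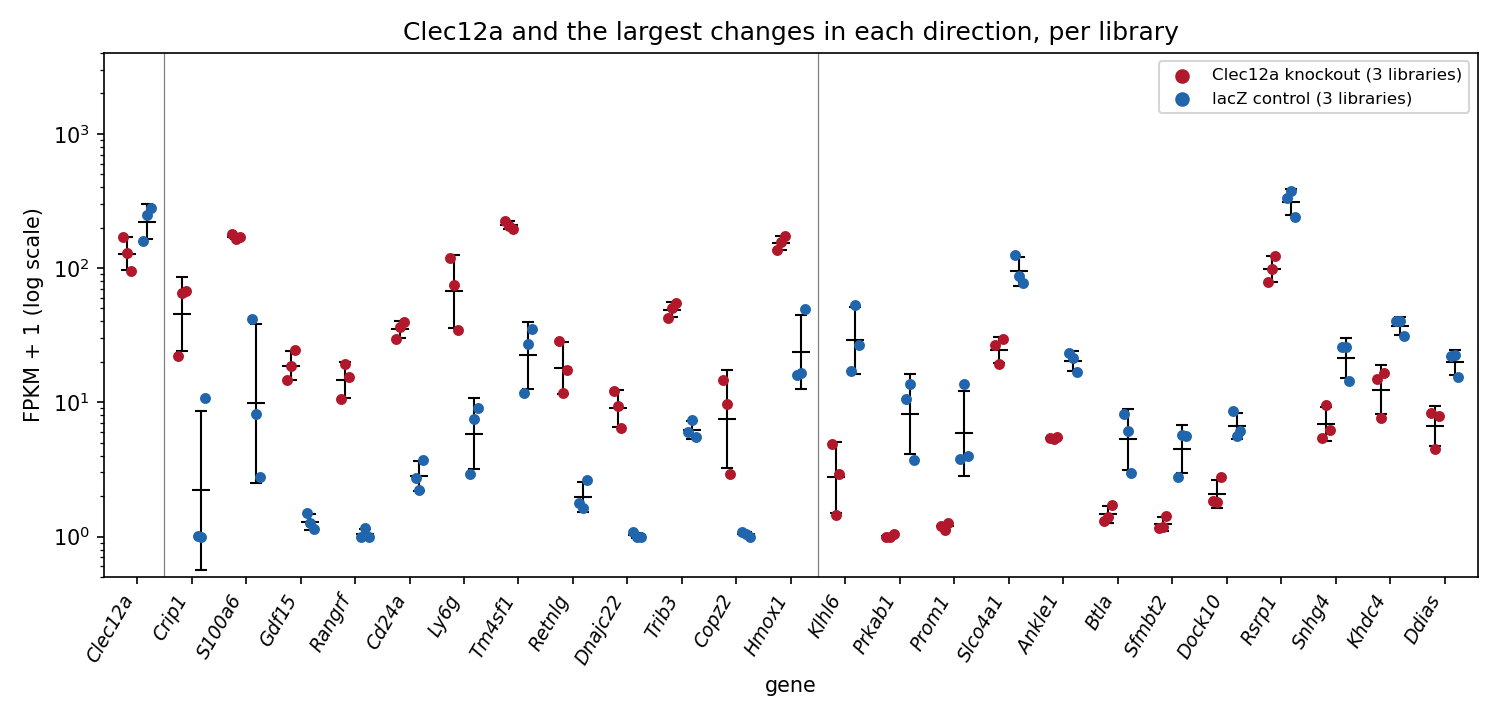
FPKM + 1 on a log axis for Clec12a and the genes with the largest rises and falls, with 1 point per library (red, 3 knockout; blue, 3 lacZ control) and bars for the mean ± SD of the log2 values. The 2 groups overlap for Clec12a, where knockout libraries lie between 94.5 and 170 FPKM and controls between 157 and 280 FPKM, and are apart for the other genes shown.

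Of 9830 genes tested, 187 changed: 136 rose and 51 fell, and 178 of them changed by at least 2-fold. At an unadjusted p under 0.05 there were 2744 genes, 1184 higher and 1560 lower, where chance gives 492. The groups did not overlap for 3568 genes (36.3%, against 10% by chance). Leaving out 1 library, and so testing fewer samples, gave 20 genes without knockout replicate 4, 37 without knockout replicate 1 and 143 without knockout replicate 5, and 92, 25 and 197 without control replicates 6, 8 and 9. Of these, 1, 3 and 27 were falls without knockout replicates 4, 1 and 5. Without control replicates 6, 8 and 9, 19, 1 and 38 were falls. With each library scaled to the same total, which shifted the median of all genes from -0.06 to -0.24, 71 genes rose and 49 fell.

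The largest rises were of single genes with different functions. S100a6, a calcium-binding protein, stood at 170 ± 6.96 against 16.6 ± 21.1 FPKM (log2 fold change 4.12, SE 0.79, adjusted p = 0.0446), and the LIM-domain gene Crip1 at 50.2 ± 25.4 against 3.23 ± 5.59 FPKM (4.37, SE 0.87, adjusted p = 0.0488). The controls differed widely for both: S100a6 was at 40.8, 7.11 and 1.78 FPKM, and Crip1 at 0.0092, 0 and 9.68 FPKM. Cd24a, a surface glycoprotein, rose by a log2 fold change of 3.62 (SE 0.25, adjusted p = 7.01e-04), the membrane protein Tm4sf1 by 3.22 (SE 0.36, adjusted p = 0.00883) and Hmox1, which degrades haem, by 2.71 (SE 0.40, adjusted p = 0.0215). Copz2, a coat protein of transport vesicles, was at 13.6, 8.76 and 1.91 FPKM in knockout libraries and at most 0.0762 in controls (adjusted p = 0.0388). After the length and GC correction, S100a6, Crip1 and Copz2 no longer passed. Dnajc22 was at 5.48 to 11.1 FPKM in knockout libraries, and controls were listed at 0.075, 0 and 0. Rangrf was at 9.54 to 18.4 FPKM against 0, 0.154 and 0, but 90.7% of its exon bases are shared with Slc25a35 on the opposite strand, and whether the counting used strand is not given in the sources used here, so its level is uncertain.

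Among the largest falls, Klhl6 went from 31.4 ± 18.7 to 2.10 ± 1.74 FPKM (log2 fold change -3.39, SE 0.51, adjusted p = 0.0215). Prkab1, a regulatory subunit of the energy sensor AMPK, was listed at 0, 0 and 0.0449 FPKM in knockout libraries and at 9.60, 12.7 and 2.74 in controls (adjusted p = 0.0204). Prom1, which encodes the stem cell surface protein CD133, fell by 2.30 on the log2 scale (SE 0.45, adjusted p = 0.0462), and the inhibitory receptor gene Btla by 1.85 (SE 0.36, adjusted p = 0.0446). The anion transporter gene Slco4a1 fell from 95.8 ± 25.4 to 24.1 ± 5.32 FPKM (adjusted p = 0.0167), and the nuclease gene Ankle1 from 19.5 ± 3.34 to 4.44 ± 0.117 FPKM (adjusted p = 0.00841). Rsrp1 fell from 314 ± 67.2 to 98.5 ± 21.9 FPKM (adjusted p = 0.0215). Sfmbt2, Dock10, Snhg4, Khdc4 and Ddias fell by 1.84, 1.67, 1.64, 1.58 and 1.56 on the log2 scale, with adjusted p from 0.0265 to 0.0458. Prom1, Btla and Sfmbt2 no longer passed after the length and GC correction.

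Among neutrophil genes, 3 that are made late in maturation rose. Of 23 tested members of the late granule and mature list, 3 rose (Ly6g, Retnlg and Lcn2), none fell and 20 did not pass, and adjusted over the list alone the count was also 3. The list was split, with 12 members higher and 11 lower and a median of 0.16. Lcn2, an iron-sequestering granule protein, rose from 18.6 ± 8.76 to 126 ± 55.0 FPKM (adjusted p = 0.0204), and Retnlg from 1.02 ± 0.544 to 18.3 ± 8.64 FPKM (adjusted p = 0.00795). The list as a whole did not pass (camera, adjusted p = 0.273), but it did without control replicate 8 (adjusted p = 0.0110), and without control replicate 6 its direction turned to lower (adjusted p = 0.885). None of 14 primary granule genes passed, and adjusted over the list alone the count was also 0 (camera, adjusted p = 0.997, with a mean of -0.39 and a median of -0.15 against a test direction of higher). Elane, the neutrophil elastase, was at 3274 ± 1400 against 1886 ± 1029 FPKM (adjusted p = 0.278) and Prtn3 at 1510 ± 707 against 1241 ± 392 FPKM (adjusted p = 0.710). Mpo, the myeloperoxidase gene, was chosen after its values were seen: it was at 0.289, 1.20 and 9.36 FPKM in knockout libraries and at 455, 737 and 10.2 FPKM in controls (log2 fold change -5.66, adjusted p = 0.0763).

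Single members of the inflammatory, JAK-STAT and RAS-MAPK lists rose. Of 25 tested cytokine and NF-kB genes, 5 rose, none fell and 20 did not pass, with 6 higher adjusted over the list alone and a list median of 0.71. Ccl4, a chemokine, rose from 226 ± 54.6 to 780 ± 209 FPKM (adjusted p = 0.0215), the NF-kB inhibitor gene Nfkbia from 119 ± 25.8 to 336 ± 16.1 FPKM (adjusted p = 0.0204) and Traf1 from 0.289 ± 0.158 to 1.81 ± 0.151 FPKM (adjusted p = 0.0292). The list passed camera (adjusted p = 5.27e-05) but not with its own correlation (adjusted p = 0.516 with an estimated correlation). Of 17 JAK-STAT targets, 3 rose and none fell, and 5 were higher adjusted over the list alone (camera, adjusted p = 1.01e-04; adjusted p = 0.516 with an estimated correlation). These were the cyclin gene Ccnd2 (75.1 ± 20.1 to 358 ± 94.5 FPKM, adjusted p = 0.0108), the cytokine gene Osm (6.53 ± 1.12 to 21.1 ± 3.20 FPKM, adjusted p = 0.0204) and the kinase gene Pim3 (21.4 ± 3.93 to 61.9 ± 21.5 FPKM, adjusted p = 0.0400). Of 24 RAS-MAPK output genes, 1 rose: Plaur, the urokinase receptor gene, from 44.1 ± 18.5 to 153 ± 13.02 FPKM (adjusted p = 0.0215). Adjusted over the list alone, 11 were higher and 1 lower (camera, adjusted p = 1.01e-04; adjusted p = 0.516 with an estimated correlation).

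Some members of the stress and p53 lists also rose. Of 23 amino acid and unfolded protein response genes, 4 rose, none fell and 19 did not pass, with 9 higher and 1 lower adjusted over the list alone (camera, adjusted p = 4.06e-04; adjusted p = 0.516 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, rose from 5.27 ± 0.957 to 48.2 ± 6.04 FPKM (adjusted p = 7.01e-04), the transcription factor gene Ddit3 from 11.96 ± 3.60 to 59.1 ± 24.6 FPKM (adjusted p = 0.0240) and Chac1, which degrades glutathione, from 3.53 ± 1.44 to 15.3 ± 3.40 FPKM (adjusted p = 0.0292). The endoplasmic reticulum gene Creld2 rose from 62.9 ± 5.73 to 146 ± 21.5 FPKM (adjusted p = 0.0263). Of 14 immediate early and stress genes, 2 rose (Hmox1 and Ddit3), and adjusted over the list alone 7 were higher and 2 lower (camera, adjusted p = 0.0321; adjusted p = 0.516 with an estimated correlation). That list's call ended without knockout replicate 5 (adjusted p = 0.0812) or control replicate 6 (0.0775), without the filter (0.181), at a mean FPKM of at least 5 (0.153), with array weights (0.0502) and after a correction for transcript length and GC content (0.0606). Of 27 p53 and cell death genes, 4 rose (Gdf15, Plk2, Cdkn2b and the death receptor gene Tnfrsf10b), 1 fell (Trp53inp1, named after its values were seen) and 22 did not pass. Adjusted over the list alone, 9 were higher and 3 lower (camera, adjusted p = 0.0114; adjusted p = 0.516 with an estimated correlation). The p53 list's call ended after the length and GC correction (adjusted p = 0.0975) and without the filter (0.182). Cdkn2b, a cell cycle inhibitor gene, went from 2.04 ± 0.643 to 6.76 ± 0.603 FPKM (adjusted p = 0.0329). Chac1, Creld2 and Cdkn2b no longer passed after the length and GC correction.

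Adhesion, glycolysis, MHC class I presentation and oxidative phosphorylation lists passed camera in the higher direction, though none did with an estimated correlation. Library medians of the members' deviations from the gene means overlapped for adhesion (0.17 in knockout replicate 5, 0.23 in control replicate 9). They also overlapped for oxidative phosphorylation (-0.05 in knockout replicate 1, 0.05 in control replicate 6). For glycolysis and MHC class I they did not overlap. Of 26 adhesion and migration genes, 4 rose (S100a6, Cd24a, the integrin gene Itgb7 and the tetraspanin gene Cd63) and none fell, with 6 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00384; adjusted p = 0.516 with an estimated correlation). Itgb7 rose from 1.32 ± 0.456 to 10.4 ± 1.31 FPKM (adjusted p = 0.00428). Of 24 glycolysis and hypoxia genes, 1 rose: Ndrg1, a hypoxia-induced gene, from 8.89 ± 1.67 to 21.9 ± 1.83 FPKM (adjusted p = 0.0353). Adjusted over the list alone, 8 were higher, and the list median was 0.73 (camera, adjusted p = 5.27e-05; adjusted p = 0.569 with an estimated correlation). None of 14 MHC class I genes passed over all genes, and 6 were higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00169; adjusted p = 0.516 with an estimated correlation). B2m, the light chain of MHC class I, was at 1023 ± 326 against 460 ± 98.0 FPKM (adjusted p = 0.0818), and H2-D1 at 840 ± 50.3 against 476 ± 134 FPKM (adjusted p = 0.0893). None of 23 oxidative phosphorylation genes passed, nor did any adjusted over the list alone (camera, adjusted p = 0.0433; adjusted p = 0.725 with an estimated correlation). Their median was 0.27, and Ndufa4 was at 600.4 ± 233 against 367 ± 174 FPKM (adjusted p = 0.238) and Atp5b at 688 ± 127 against 670.0 ± 136 FPKM (adjusted p = 0.929). That list's call ended without knockout replicate 4 (adjusted p = 0.141), knockout replicate 5 (0.0949), control replicate 8 (0.0781) or control replicate 9 (0.2001). It also ended after the length and GC correction (0.825), with quantile normalization (0.786), equal totals (0.0995) or array weights (0.237), and without the filter (0.158).

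Both cell division lists passed camera in the lower direction, though not with an estimated correlation. Of 26 G2 and M phase genes, 2 fell, none rose and 24 did not pass, while adjusted over the list alone 18 were lower. The 2 were motor protein genes of cytokinesis: Kif20a fell from 83.5 ± 7.89 to 35.9 ± 10.3 FPKM (adjusted p = 0.0465) and Kif23 from 40.2 ± 8.43 to 18.7 ± 1.502 FPKM (adjusted p = 0.0467). The list median was -0.73, with 25 of 26 members lower (camera, adjusted p = 1.91e-07; adjusted p = 0.516 with an estimated correlation). Of 24 S phase genes, 1 fell, the cyclin gene Ccne2 (45.3 ± 4.11 to 16.5 ± 5.02 FPKM, adjusted p = 0.0353), and 6 were lower adjusted over the list alone (camera, adjusted p = 4.06e-04; adjusted p = 0.516 with an estimated correlation). None of 21 cholesterol synthesis genes passed, nor did any adjusted over the list alone, but 19 had lower values (camera, adjusted p = 0.00460; adjusted p = 0.694 with an estimated correlation). Sqle was at 89.4 ± 29.4 against 138 ± 17.5 FPKM (adjusted p = 0.152) and Fdps at 562 ± 126 against 442 ± 122 FPKM (adjusted p = 0.387). The cholesterol list's median deviation from the gene means was 0.04, -0.64 and -0.08 in knockout replicates 1, 4 and 5. In control replicates 6, 8 and 9 it was 0.18, 0.45 and 0.07. Knockout replicate 4 was thus the lowest by far, though the list still passed without it (camera, adjusted p = 0.0246). None of 26 MYC and ribosome biogenesis genes passed, nor did any adjusted over the list alone (camera, lower, adjusted p = 0.0236; adjusted p = 0.724 with an estimated correlation). Npm1 was at 703 ± 223 against 751 ± 233 FPKM and Ldha at 1683 ± 125 against 1074 ± 174 FPKM. That list's call ended without knockout replicate 1 (adjusted p = 0.112), knockout replicate 5 (0.0956) or control replicate 6 (0.247).

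**Figure D2:**
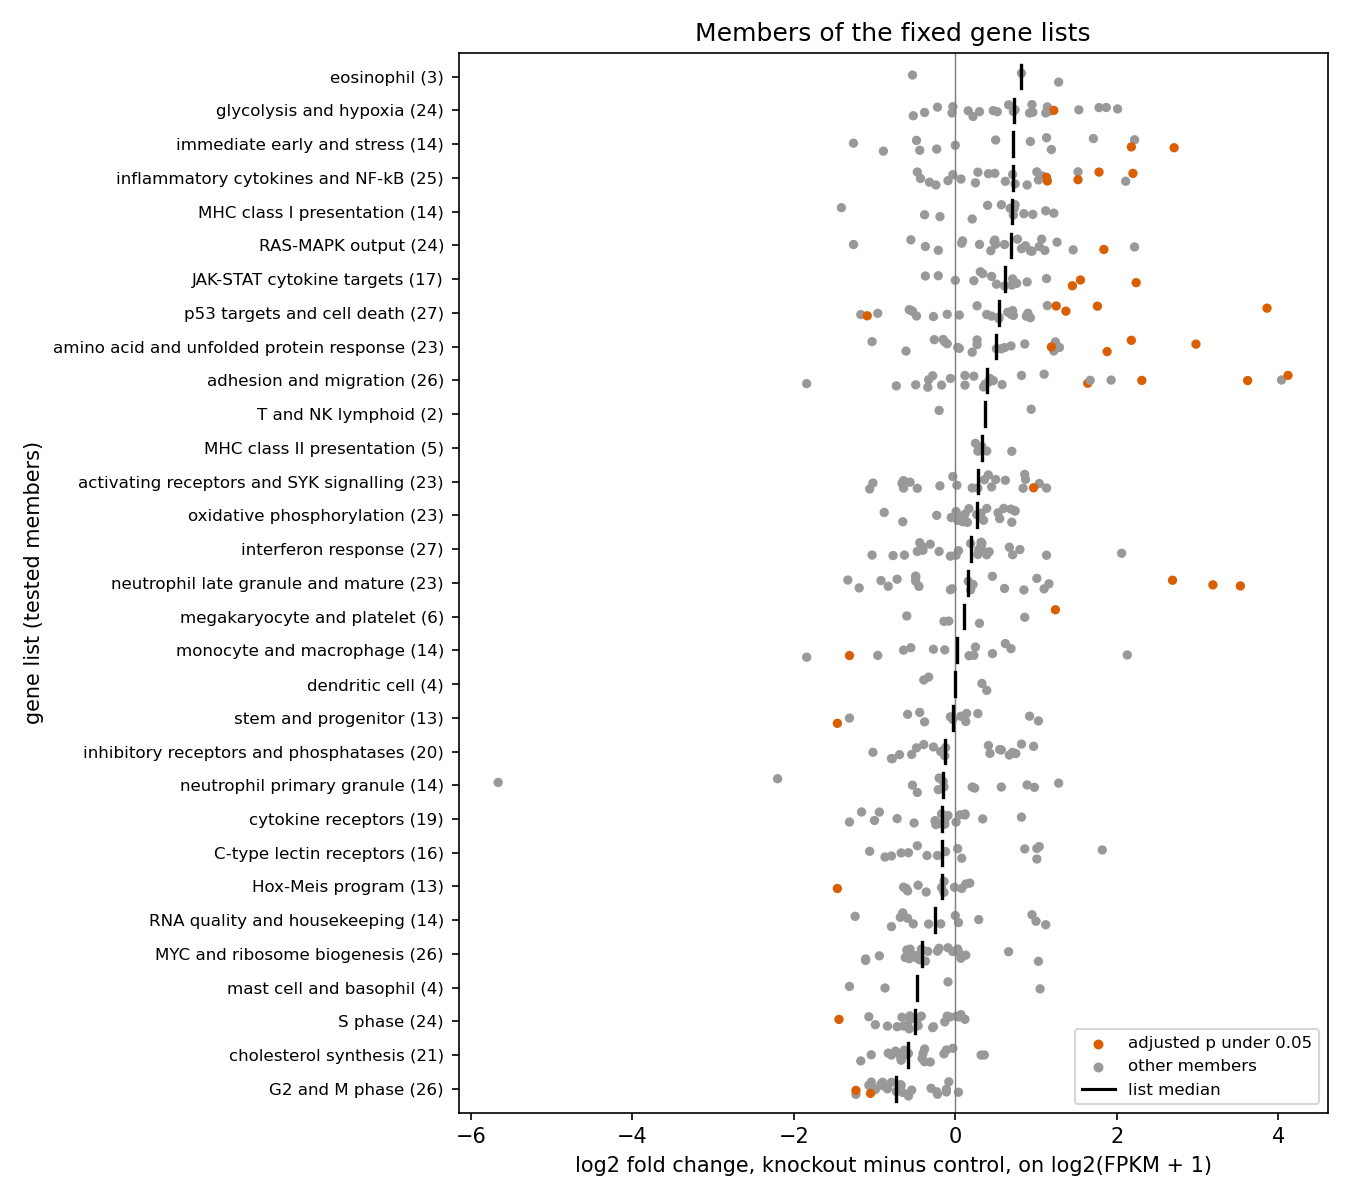
Log2 fold change (knockout minus control) of each tested member of the gene lists with more than 1 tested member, with the number tested in brackets; orange points had an adjusted p under 0.05, grey points did not, and black bars are list medians. The G2 and M phase list has the lowest median (-0.73), and points to the right of 3 include Ly6g (3.53), Cd24a (3.62), Gdf15 (3.86) and S100a6 (4.12).

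Single genes of stem cells, other blood lineages and receptors changed in lists that did not pass. Meis1 was the 1 gene to fall among 13 stem and progenitor genes (camera, adjusted p = 0.843) and among 13 Hox-Meis genes (camera, adjusted p = 0.105). The Hox-Meis list passed, lower, without knockout replicate 4 (adjusted p = 0.0341) or control replicate 6 (0.0457). Adjusted over the list alone, 1 Hox-Meis gene was lower, and 1 stem and progenitor gene was higher and 1 lower. Kit, the stem cell factor receptor, differed between libraries within each group: it was at 0.736, 1.18 and 6.66 FPKM in knockout libraries and at 27.6, 8.03 and 0.715 FPKM in controls (adjusted p = 0.374). Apoe fell, from 10.5 ± 2.19 to 3.61 ± 0.692 FPKM (adjusted p = 0.0397), as 1 of 14 monocyte and macrophage genes (camera, adjusted p = 0.989). Adjusted over the list alone, 1 of those was higher and 2 lower, and the list's median was 0.02 and its mean -0.08. Selp rose from 0.0328 ± 0.0205 to 1.48 ± 0.558 FPKM (adjusted p = 0.0294) as 1 of 6 megakaryocyte genes (camera, adjusted p = 0.438), with 1 higher and 1 lower adjusted over the list alone. Lcp2, an adaptor of activating receptors, rose from 84.7 ± 2.67 to 168 ± 25.1 FPKM (adjusted p = 0.0444) as 1 of 23 activating receptor and SYK genes (camera, adjusted p = 0.273), with 4 higher and 3 lower adjusted over the list alone. That list passed, higher, without control replicate 9 (adjusted p = 0.0370).

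None of 16 tested C-type lectin genes passed over all genes, but adjusted over the list alone 4 were higher and 4 lower (camera, adjusted p = 0.997, with a median of -0.17 and a mean of 0.04). Clec5a, which signals through DAP12, was at 1083 ± 126 against 540 ± 160 FPKM (adjusted p over all genes = 0.0736), with Clec4d, Clec4e and Clec10a also higher by log2 1.01, 0.86 and 1.82. Besides Clec12a, the lower ones were Clec4n (log2 fold change -1.06), Cd69 (-0.87) and Olr1 (-0.67). None of 20 inhibitory receptor and phosphatase genes passed, nor did any adjusted over the list alone (camera, adjusted p = 0.688, with a median of -0.13 and a mean of 0.02). In that list Lilrb4a was at 523 ± 73.9 against 340 ± 142 FPKM and the phosphatase gene Ptpn6 at 265 ± 43.9 against 299 ± 35.2 FPKM. None of 19 cytokine receptor genes passed, nor did any adjusted over the list alone (camera, adjusted p = 0.438): Ifngr1 was at 329 ± 40.2 against 373 ± 33.2 FPKM and Csf2ra at 132 ± 26.1 against 126 ± 52.6 FPKM. None of 27 interferon response genes passed, and 1 was higher adjusted over the list alone (camera, adjusted p = 0.438): Ifitm3 was at 663 ± 308 against 631 ± 242 FPKM.

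Markers of other cell types were few among the tested genes, and none passed in the lists that follow. Of 5 MHC class II genes (camera, adjusted p = 0.169, but 0.0490 without control replicate 9 and 0.00386 without the filter), H2-DMb1 was at 67.2 ± 15.5 against 53.9 ± 15.2 FPKM and H2-DMa at 12.8 ± 3.11 against 10.3 ± 2.29 FPKM. Of 4 dendritic cell genes (camera, adjusted p = 0.957), Cst3 was at 249.9 ± 47.0 against 199.9 ± 49.9 FPKM and Bst2 at 70.2 ± 24.0 against 51.7 ± 5.29 FPKM. Of 4 mast cell genes (camera, adjusted p = 0.997), Srgn was at 1139 ± 339 against 547 ± 159 FPKM (adjusted p = 0.0857). Of 3 eosinophil genes (camera, adjusted p = 0.273), Siglecf was at 3.00 ± 0.429 against 1.27 ± 0.330 FPKM and Cebpe at 66.5 ± 36.0 against 30.7 ± 21.05 FPKM. Of 2 T and NK cell genes (camera, adjusted p = 0.283), Lck was at 1.72 ± 0.395 against 0.422 ± 0.206 FPKM and Nkg7 at 2.67 ± 1.15 against 3.92 ± 3.26 FPKM. The erythroid list had Tfrc alone (41.9 ± 17.9 against 92.5 ± 32.5 FPKM; camera, adjusted p = 0.273) and the stroma and endothelium list Pecam1 alone (88.2 ± 19.6 against 58.4 ± 9.62 FPKM; camera, adjusted p = 0.273). Adjusted over each list alone, 1 gene was higher in the mast cell, eosinophil, T and NK cell and stroma lists, 1 lower in the erythroid list and 0 in the MHC class II and dendritic lists. For Tfrc and Pecam1, each alone in its list, this is the unadjusted p, and the groups overlapped for both. Of all 9830 tested genes, 2744 had an unadjusted p under 0.05. No member of the B lymphoid list (14 genes) or the sex-linked list (5 genes) was tested.

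The libraries also differed in overall properties. Of 14 RNA quality and housekeeping genes none passed, and 2 were higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.659, but 0.0449, lower, with quantile normalization); Actb was at 7100 ± 647 against 3636 ± 1132 FPKM (adjusted p = 0.115) and Ppia at 2107 ± 579 against 2016 ± 394 FPKM (adjusted p = 0.940). A library's deviation from the gene mean ranked with transcript length (Spearman's rho across genes, which are not independent replicates) at -0.06, -0.45 and -0.16 in knockout libraries and at 0.29, 0.28 and 0.31 in controls. Knockout replicate 4 lay farthest out on the first principal component (-55.2, against -23.1 and -9.2 for the other knockout libraries), and without it the gene counts in the lists above were 2 for adhesion, 1 each for the amino acid, inflammatory, JAK-STAT, late granule and p53 lists, and 0 for the others. Without it 14 lists passed camera, among them G2 and M phase (adjusted p = 8.11e-10), glycolysis (5.10e-07) and RAS-MAPK output (1.82e-05). Of the 10 possible splits of the 6 libraries into 3 and 3, 3 put at least 14 lists past camera's threshold, the real split included.

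Genes at the distal end of chromosome 15 were higher together in knockout cells. Medians and shares of genes in this paragraph are relative to the median of all genes (-0.06), unless another reference is given. The interval ran from 83483769 to 103498810 (GRCm38) and was delimited after the data were seen. Its start was placed where the same fold changes, corrected for length and GC content, set distal genes most apart from proximal ones. The values below therefore describe the interval and do not test it. The median log2 fold change of its 134 tested genes was 0.54 (95% bootstrap interval over genes 0.44 to 0.67), and 87.3% of them lay above the median of all genes. Over the 96 of these genes with a mean FPKM of at least 5, and relative to genes elsewhere, the median was 0.52, 0.56 and 0.52 in the knockout libraries, each set against the control mean, and -0.02, 0.03 and 0.03 in the controls, each set against the other 2 controls. By the test of single genes, 18 of the 134 rose (13.4%, against 1.2% elsewhere) and 0 fell. Dnajc22, Pim3, Creld2 and Itgb7, named above, lie in this interval. The rest of the chromosome, with 256 tested genes, had a median of 0.02 on the same relative scale, and Ly6g and Ndrg1 lie there.

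**Figure D3:**
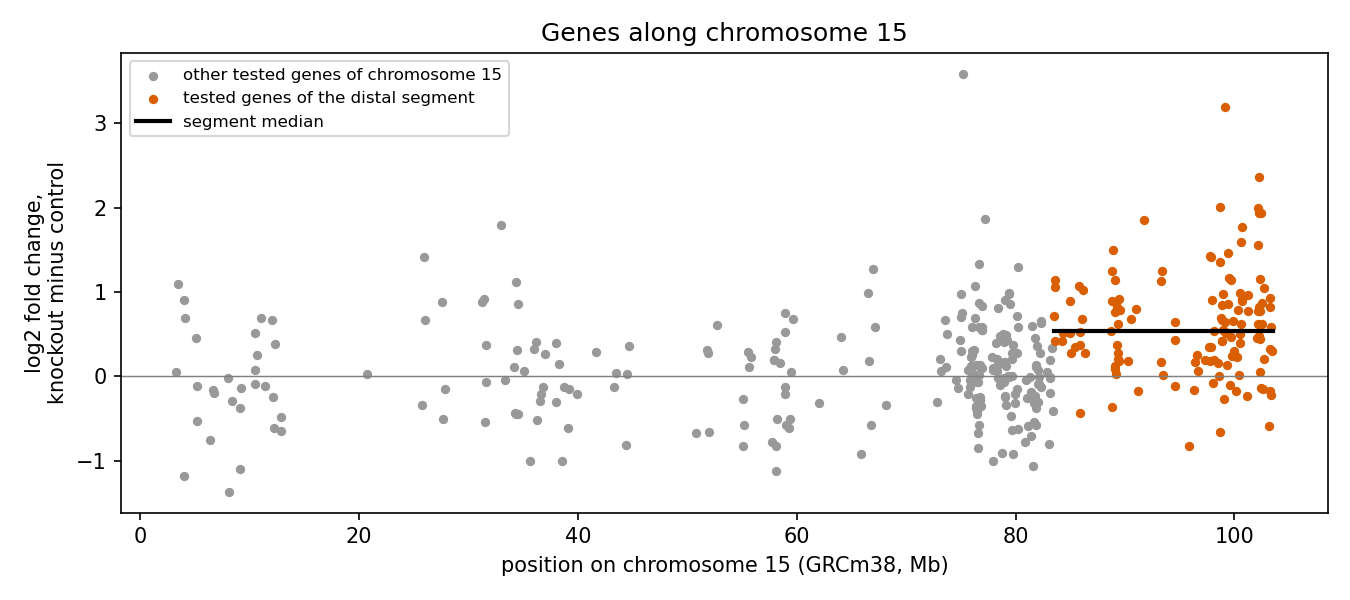
Log2 fold change (knockout minus control, relative to the median of all genes) of tested genes by position on chromosome 15 in Mb, with the 134 genes of the distal interval in orange, the others in grey and the interval's median (0.54) as a black line. Most orange points lie above 0, and the grey points have a median of 0.02.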

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

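The correction for transcript length and GC content and the fits without distal chromosome 15 were chosen after the results were seen; the other alternatives were planned. Against 187 changed genes, there were 122 with a pseudocount of 0.01, 23 without the filter, 97 at a mean FPKM of at least 5 (fewer genes tested), 120 with equal totals, 4154 with array weights and 1106 at an adjusted p under 0.1. Leaving out 1 library (fewer samples) gave 20 (knockout replicate 4) to 197 (control replicate 9), with 37 without knockout replicate 1, 25 without control replicate 8 and 92 without control replicate 6. The array weights were 7.21 for control replicate 8 and 2.54 for knockout replicate 1, and 0.21 to 0.87 for the other libraries. That fit therefore leaned on 1 library per group. Each leave-one-out fit lacked 1 library, yet their counts ran from 20 to 197, so fewer samples alone do not explain them. At a mean FPKM of at least 5, 134 of the 187 genes were still tested and 97 passed. Fewer tested genes therefore do not alone explain that count. The causes of the differences in the counts were not tested. Clec12a had log2 fold changes of -1.04 to -0.57 and passed only with array weights (-0.66, adjusted p = 0.0342; adjusted p over the other alternatives 0.0764 to 0.349). Of 14 lists past the threshold, 0 passed with an estimated correlation and 2 with fry; other settings gave 11 to 15 lists. No paired analysis was possible because the replicate numbers share none between groups. Estimated depths of 33600000 to 61000000 fragments leave genes near 0 FPKM least certain.

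Many named genes that had passed lost their call. Of 49 such genes, 43 did without the filter, 39 without knockout replicate 4, 38 without control replicate 8, 35 without knockout replicate 1, 22 without control replicate 6, 18 without knockout replicate 5, 11 without control replicate 9, 11 with equal totals, 9 and 8 with pseudocounts of 0.01 and 0.1, 4 with quantile normalization and 1 with median ratios. At a mean FPKM of at least 5, 6 of 37 did, and without distal chromosome 15, 5 of 45. With the length and GC correction 12 of 48 did: Crip1, S100a6, Copz2, Prom1, Btla, Sfmbt2, Meis1, Ccne2, Kif23, Cdkn2b, Creld2 and Chac1 (adjusted p from 0.0522 for Ccne2 to 0.0710 for Cdkn2b). The largest losses came with fewer samples or with genes near 0 kept; the cause was not tested.

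Of 36 named genes besides Clec12a that had not passed, 19 passed with array weights. Without control replicate 9 there were 2 such gains, and with the length and GC correction 1. Named genes that had not passed changed sign as follows (log2 fold change, with the cause not tested). With quantile normalization: Prtn3 -0.20, Ifitm3 -0.28, Csf2ra -0.01, Atp5b -0.32 and Ppia -0.45. With equal totals: Ifitm3 -0.16, Csf2ra -0.09, Atp5b -0.16 and Ppia -0.16. With array weights: Prtn3 -0.42, H2-DMa -0.02, Ifitm3 -0.02, Ifngr1 0.05, Atp5b -0.18, Fdps -0.07 and Ppia -0.38. With the length and GC correction: Prtn3 -0.35, Cst3 -0.24, Bst2 -0.17, H2-DMb1 -0.05, Ifitm3 -0.48, Csf2ra -0.10 and Atp5b -0.17. Leaving out 1 library gave Prtn3 -0.12 to 0.53, Nkg7 -0.84 to 0.31, Ifitm3 -0.31 to 0.33, Csf2ra -0.11 to 0.43, Npm1 -0.37 to 0.15, Atp5b -0.11 to 0.19 and Ppia -0.13 to 0.28.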

Other observations

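All gene groups and tests in this part were chosen after the results were seen, except that what would count for or against each account of the construct genes was set before its test was run. Because the lists in this paragraph were assembled after the falls and rises of their members were seen, only counts and values are given for them, and no list is called changed. Of 37 tested genes listed for RNA splicing and nuclear speckles, 6 fell (Rsrp1, Pnisr, Leng8, Prpf38b, Fnbp4 and Ogt), none rose and 31 did not pass; 32 had lower values, with a median of -0.41. Leng8 went from 22.9 ± 0.451 to 8.13 ± 2.81 FPKM and Prpf38b from 62.1 ± 10.7 to 27.3 ± 2.24 FPKM (SD, n = 3 each). Of 26 kinetochore and centromere genes, 2 fell (Knl1 and Kif20b, by 1.32 and 1.52 on the log2 scale). All 13 mitochondrially encoded genes had lower values, with a median of -0.63, but 1 fell, mt-Nd4l. The deviation of these genes was lowest in knockout replicate 5 (-0.99). It was -0.13 and 0.11 in knockout replicates 1 and 4. In control replicates 6, 8 and 9 it was 0.38, 0.51 and -0.02, so the groups overlapped. Of 8 tubulin genes 1 rose, Tuba1a, from 62.7 ± 6.43 to 119 ± 9.002 FPKM; Tuba1a, Tuba1b and Tuba1c lie in the distal chromosome 15 interval. Of 28 lysosome genes 0 rose, and of 11 iron genes 1 rose.

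Some myeloid surface genes did not pass the threshold despite large differences between libraries. Cd14, a co-receptor for lipopolysaccharide, was at 325, 471 and 323 FPKM in knockout libraries against 60.5, 51.4 and 185 (adjusted p = 0.0513). Ccr2, a chemokine receptor of monocytes, was at 124, 65.0 and 82.4 FPKM against 191, 299.9 and 551 (adjusted p = 0.0520). Cd9 was at 68.6, 37.2 and 1.03 FPKM in knockout libraries and at 0, 0.018 and 94.0 in controls (adjusted p = 0.502). Values by library in the next 2 intervals are over genes with a mean FPKM of at least 5, relative to genes elsewhere, with knockout libraries set against the control mean and each control against the other 2. The bounds of both intervals were placed on differences between these same libraries. On chromosome 4, between 83455680 and 124849800 (GRCm38), 118 such genes had a median of 0.57 in control replicate 8 and of -0.33 to -0.23 in the other libraries. Control replicate 8 is part of the reference of each other library, so their negative values follow at least in part from its own. On proximal chromosome 6 (3372257 to 29541871), 53 tested genes had a median log2 fold change, relative to the median of all genes, of 0.40, or 0.49 after the length and GC correction, and 43 genes at a mean of at least 5 had medians of 0.41, 0.16 and 0.63 in knockout replicates 1, 4 and 5 and 0.35, -0.19 and -0.24 in control replicates 6, 8 and 9; Clec12a lies outside this interval.

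The rise of genes on distal chromosome 15 was weighed against a library trend, chance and a difference in DNA copies. After each library was corrected for transcript length and GC content the median, relative to that of all genes, was 0.50 (95% bootstrap interval 0.45 to 0.56). The interval's start was placed on these corrected values, so its median cannot by itself argue against that trend. Windows of 60 genes, by contrast, were laid by gene order alone. The largest corrected median among them, 0.55, lay on distal chromosome 15, which argues against that trend. Of 10000 shuffles of gene order, 0 gave a window of 60 genes as far from 0 (permutation p = 1e-04, the smallest they can give), which argues against a chance order. A copy-number difference shared by a group needs a like shift in each of its libraries. Single libraries can also stand apart, as an interval of chromosome 4 did in control replicate 8 (0.57 against the other 2 controls). On distal chromosome 15 the lowest knockout median against the control mean was 0.52, where 3 copies against 2 would give 0.58. A copy-number difference between the groups is therefore a candidate explanation. Values set against the controls do not say which group departs from 2 copies, and whether the difference came from a shared ancestor of the knockout cells or has any link to the Clec12a edit on chromosome 6 was not tested.

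The 187 changed genes were weighed against chance, a library trend and chromosome 15. Only 10 splits of 6 libraries into 3 and 3 exist, too few for a share under 0.05; the real split gave 187 genes (1 of the 10 splits gave as many) and the highest other split 1 gene. For gene lists the real split put 14 past the threshold, but 3 of the 10 splits gave as many, and the highest other split, knockout replicate 1 with control replicates 6 and 8, gave 20, so the list results may follow differences among libraries as much as the guide. After the length and GC correction, 124 of 186 genes stayed past the threshold, which argues against that trend as the whole cause. By position, 169 of the 187 lie outside distal chromosome 15, where copies of that interval acting on its own genes do not reach. With 134 tested genes the interval could not have held all 187, so this count describes the genes and is no test. Effects of that interval on genes elsewhere and differences between single sorted cells that predate the edit were not tested and stay open beside loss of Clec12a.

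Nup98, Nsd1 and Nras, the genes of the introduced fusion and oncogene, were low in knockout replicate 4: 5.92, 7.10 and 314 FPKM, against 23.6 to 32.8, 21.2 to 34.6 and 697 to 958 in the other 5 libraries. Among the 500 genes nearest in length and GC content their deviations in that library were at percentiles 1.4, 1.6 and 9 (mean 4), which argues against a length and GC trend for Nup98 and Nsd1 more than for Nras. Their 20 nearest genes on the chromosome had medians of 0.02, 0.24 and -0.46 (the lowest), within the 0.5 set in advance, so a loss of those regions is less likely and fewer reads from the introduced constructs are a candidate explanation. Reads from constructs and from the cells' own genes were not told apart. No biological explanation was tested for this library.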
